A study of Homo sapiens with 4 samples.

How the data were processed

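Poly(A) RNA of HepG2 cells was sequenced as input (2 samples) and after m7G immunoprecipitation (2 samples), per the labels' protocols, from stranded mRNA libraries on an Illumina instrument. STAR and the build GRCh38 are named, per the submitters' processing notes, without a version or a stated role. The peak caller, its filters and the read numbers are not given in the sources used here. The analysis used the authors' 2 peak lists, 1 per IP sample; input values were not analysed here, so IP was not set against input again.

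Each deposited list gives, per the file headers, a peak's position, strand, gene name, exon blocks, p-value, log10 p, log10 FDR and fold enrichment. The p-value is the authors' own; it is listed as 0 for 9 peaks of replicate 1 and 4 of replicate 2, and the log10 p was therefore used for ranking. The log10 p and log10 FDR are used as scores of the authors' caller; the deposited log10 p scores matched the log10 of the p-value within 0.02. The weakest FDR in either list had a -log10 of 1.32, so the deposited lists stop near an FDR of 0.05. The deposited fold is a ratio per peak and is above 1 for every peak; the authors' scaling and the libraries it compares are not named in the headers. A fold, p-value or length is thus each peak's own value from the authors, and was used to describe, rank or filter peaks. Each deposited list belongs to 1 IP sample, per the labels. Repeated positions under different gene names (1 in replicate 1 and 5 in replicate 2) were kept as deposited. Reads of near-identical genes cannot be told apart from these lists.

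Gene names were matched to a RefSeq gene table of GRCh38.p14 by symbol (3213 peaks of replicate 1, 4540 of replicate 2) or by an older symbol at the same place (139 and 201); 3 and 6 peaks did not match and were left out of positions. Symbols are given in their current form. Of matched peaks, 99.1% in replicate 1 and 99.2% in replicate 2 overlapped the span of the named gene, which checks that both use the same coordinates. No exon or UTR models and no genome sequence were used, so position was measured as the genomic distance of the peak's midpoint, taken along its blocks, from the ends of the gene's span. The planned classes of UTR and coding sequence, the sequence motifs and the choice of transcript could not be analysed.

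Peaks of the lists were called shared when they lay in the same gene on the same strand and overlapped by at least 50% of the shorter peak in exon blocks. The planned null for overlap, random placement along the peak-covered sequence of a gene, did not recover planted overlap in simulated lists. It was replaced, after the lists were seen, by exchanging the distances to the gene's end between genes, for single-block peaks within 1000 nt of an end (1000 exchanges, one-sided). An excess of 5'-end over 3'-end peaks, each with a midpoint in the last 200 nt of the span at that end or beyond it, was tested by mirroring all peaks of a gene at random (1000 draws, two-sided). Median folds were compared by permutation (100000 resamples, two-sided), and folds of shared peaks by Spearman's rho with a permutation p. Gene lists (20) were tested with Fisher's exact test on genes with a peak in both lists among genes with a peak in either, since genes without a peak can be unexpressed. Adjusted p-values are Benjamini-Hochberg values over the family named. No test across the 2 replicates was run. Tests over peaks or genes describe these lists, and the labels do not say whether the spread between them is technical. Wilson intervals (95%) cover counting error only.

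The gene lists and the planned tests were fixed before the data were examined; tests and settings chosen later are named as such. Genes named are the 25 whose shared peak had the best lower rank by fold in the 2 lists, up to 4 per gene list by the same ranking, and METTL1, WDR4 and QKI; some genes that this rule names are not reported here. The statistics were tested on simulated data: planting 20% copied peaks raised the overlap above exchange by 12.1 percentage points at the 5' end (731 peaks) and 9.12 at the 3' end (342 peaks), and a list planted at a probability of 0.9 was called in 42 of 50 draws over 3769 genes, with 1 list called in 50 draws without any planted list. For partners at equal length (899 peaks of 100 nt or less), a planted difference of 0.2 gave 22.1 percentage points and no planted difference 3.79. Alternatives were stricter peak sets, other overlaps, each replicate alone, shared peaks, every base in place of midpoints, other windows, long genes and other bases for the gene lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.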

Results

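HepG2, a human hepatocellular carcinoma cell line, was profiled without treatment by m7G MeRIP-seq, in which poly(A) RNA is pulled down with an antibody against N7-methylguanosine and sequenced beside the input RNA. The design comprised 2 input samples and 2 m7G immunoprecipitation (IP) samples. The values analysed here are the authors' peak lists of the 2 IP samples, in which a peak is a stretch of an mRNA called as enriched, with its own p-value and fold enrichment. Read depth is unknown from these lists, so no counting interval is given for a single peak's fold. The labels do not say whether the 2 IP samples came from separate cultures. Replicate 1 held 3355 peaks in 2511 genes and replicate 2 held 4747 peaks in 3205 genes, 1.41 times as many peaks. The median peak length was 151 nt in both lists, and 26.4% of replicate 1 peaks and 28.2% of replicate 2 peaks were spliced, that is, joined more than 1 genomic block. The median fold enrichment was 3.71 in replicate 1 (interquartile range 2.39 to 5.77) and 3.87 in replicate 2 (2.60 to 5.87).

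The first comparison asked which mRNAs carried m7G peaks in both IP samples. A total of 1947 genes had peaks in both lists, which was 51.7% of the 3769 genes with a peak in either (95% Wilson interval 50.1 to 53.3%). These were 77.5% of the replicate 1 genes and 60.7% of the replicate 2 genes. The peaks with the highest fold in both lists lay in mRNAs of varied function. ZFP91, a zinc finger protein with ubiquitin ligase activity, had a peak on chromosome 11 (GRCh38) from 58579144 to 58579443 with a fold of 66.8 in replicate 1, and from 58579144 to 58579593 with a fold of 42.2 in replicate 2. PKP4, a catenin-family junction protein, had folds of 51.9 and 38.0, and the tetraspanin TSPAN33 had folds of 27.8 and 75.9. MAPK3, which encodes the kinase ERK1, had folds of 32.6 and 18.7 at a spliced peak on chromosome 16 from 30121981, which ended at 30123279 in replicate 1 and 30123309 in replicate 2. Genes of transcription and chromatin in this group were AEBP2, a cofactor of Polycomb repressive complex 2 (26.0 and 35.8), NELFB, a subunit of the negative elongation factor (15.5 and 22.0), the Notch coactivator MAML1 (13.4 and 31.6), and the zinc finger genes PATZ1 (16.7 and 23.7) and ZNF787 (15.3 and 18.0). Genes of RNA handling were THOC6, part of the THO mRNA export complex (19.1 and 23.2), and CLK2, a kinase of SR splicing factors (37.1 and 15.8). Genes of membrane lipids and trafficking were the lipid kinases PIP4K2B (17.3 and 42.2) and PI4K2B (14.8 and 25.3) and the adaptor subunit AP3S1 (16.2 and 25.3). NCKAP1, a component of the actin-regulating WAVE complex, had a fold of 19.0 in both lists, and COL6A1, a collagen VI chain, had folds of 21.0 and 16.4. Others of these 25 genes were FBXL19, HDGFL2, ROGDI, SSBP3, ANKS1A, GPSM1, LRRC1 and KCMF1, with folds between 14.8 and 37.1. Within these 25 genes the -log10 p ranged from 3.49 for GPSM1 in replicate 2 to 117 for ZNF787 in replicate 2, and across all peaks fold and -log10 p were weakly ranked together (Spearman's rho = 0.039 in replicate 1 and 0.13 in replicate 2). Fold values recurred within each list, 7.42 at 107 peaks of replicate 1 and 6.33 at 196 peaks of replicate 2, and 11 of these 25 genes, PKP4 and CLK2 among them, had folds in both lists equal, within rounding, to that value times a ratio of whole numbers up to 10. Of the genes named in advance, QKI, an RNA-binding protein, had a peak on chromosome 6 from 163414643 in both lists. It ended at 163415302 in replicate 1 (fold 4.47) and was spliced on to 163570716 in replicate 2 (fold 8.19), whereas METTL1 and WDR4, the subunits of an m7G methyltransferase, had 0 peaks in either list, which does not separate a lack of m7G from low expression.

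At the level of sites, 2183 of the 3355 replicate 1 peaks (65.1%, 95% Wilson interval 63.4 to 66.7%) and 2155 of the 4747 replicate 2 peaks (45.4%, 44.0 to 46.8%) overlapped a peak of the same gene in the other list by at least 50% of the shorter peak. Matched one to one, these gave 2128 shared peaks in 1708 genes. Where a gene had an unspliced peak within 1000 nt of its 5' end in both lists, 89.5% of the 731 replicate 2 peaks overlapped a replicate 1 peak, compared with 44.2% when the distances to the 5' end were exchanged between genes. At the 3' end the values were 85.4% of 342 peaks and 32.2%. Both exceeded every exchange (one-sided permutation test, p = 0.001, the smallest that 1000 exchanges can give). The exchange ignores the exons and coverage of each gene, which both lists share and which can raise the overlap. The excess over it is thus not by itself agreement on m7G sites. Requiring 80% reciprocal overlap lowered the shares to 23.8% of replicate 1 peaks and 16.8% of replicate 2 peaks.

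The strength of enrichment at shared peaks was compared next. The fold enrichment of replicate 1 ranked with that of replicate 2 across the 2128 shared peaks (Spearman's rho = 0.80, permutation p = 1e-05 with 100000 resamples, the smallest they can give, adjusted p = 1e-05 over 3 quantities), where peaks are not independent replicates. The libraries behind the folds are not named, so an input used for both lists could by itself give a positive rho. The folds of 72.6% of shared peaks lay within 1.5 times of each other, and 10.8% differed by more than 2 times. The splicing regulator HNRNPL had folds of 7.02 and 6.80, and PTBP1, the polypyrimidine tract-binding protein, had 6.20 and 7.64. The -log10 p ranked less closely (rho = 0.66), as did peak length (rho = 0.56).

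**Figure D1:**
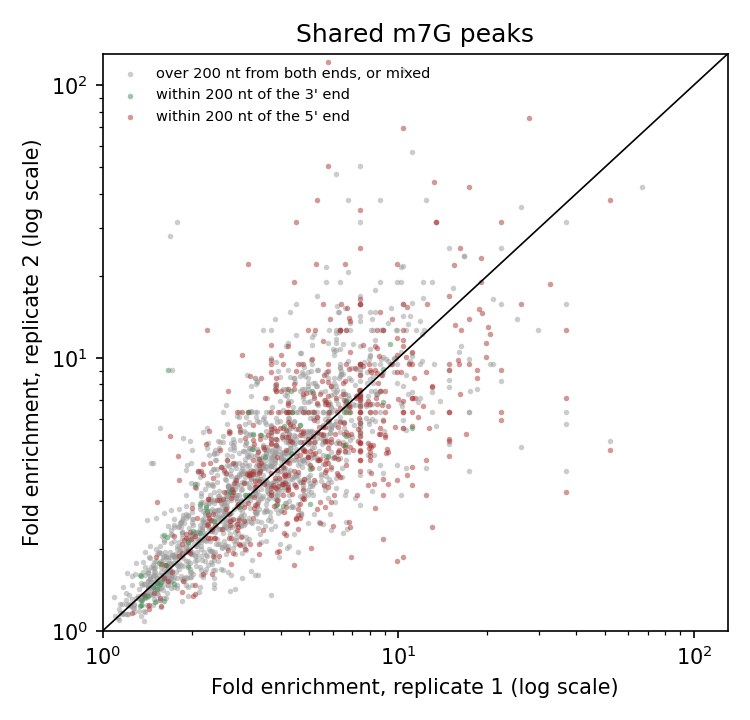
Fold enrichment of each of the 2128 shared peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), coloured by position in the gene, with the line of equal fold. Most points lie near the line (72.6% within 1.5 times), and 10.8% differ by more than 2 times.

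The position of peaks along genes was then examined from the distance of each peak's midpoint to the ends of the gene's span. Peaks concentrated at the 5' end of genes. In replicate 1, 918 of 3352 peaks (27.4%, 95% Wilson interval 25.9 to 28.9%) had a midpoint within 200 nt of the 5' end and 115 (3.43%, 2.87 to 4.10%) within 200 nt of the 3' end. In replicate 2 the numbers were 1024 of 4741 (21.6%, 20.5 to 22.8%) and 165 (3.48%, 3.0 to 4.04%). Midpoints beyond the annotated end were counted with that end; 15 and 11 peaks at the 5' end and 1 and 4 at the 3' end, in replicates 1 and 2, lay more than 200 nt outside the gene's span. The mean over replicates was 24.5% ± 4.09 (SD, n = 2) at the 5' end and 3.46% ± 0.035 (SD, n = 2) at the 3' end. The excess at the 5' end was larger than in any of 1000 random mirrorings of the genes in each list (two-sided permutation test, p = 0.001, the smallest they can give). Among the genes named above, 5'-end peaks were found in PKP4, TSPAN33, THOC6, NELFB, MAPK3 and MAML1; they were also present in SCD, a fatty acid desaturase, PFN1, which encodes profilin, and XBP1, a transcription factor of the unfolded protein response. The remaining peaks lay away from both ends, 69.2% of replicate 1 and 74.9% of replicate 2. They included PTBP1 on chromosome 19 from 811045, whose midpoint was 1058 nt from the 3' end in replicate 1, and IGF2, an insulin-like growth factor, with folds of 4.17 and 4.22 at 922 nt from the 3' end in replicate 1. IGF2 was chosen after its values were seen. Whether a peak lies in a UTR or coding sequence was not analysed here. Distances are genomic, so introns between a peak's midpoint and the gene's end are included, for spliced and unspliced peaks alike.

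**Figure D2:**
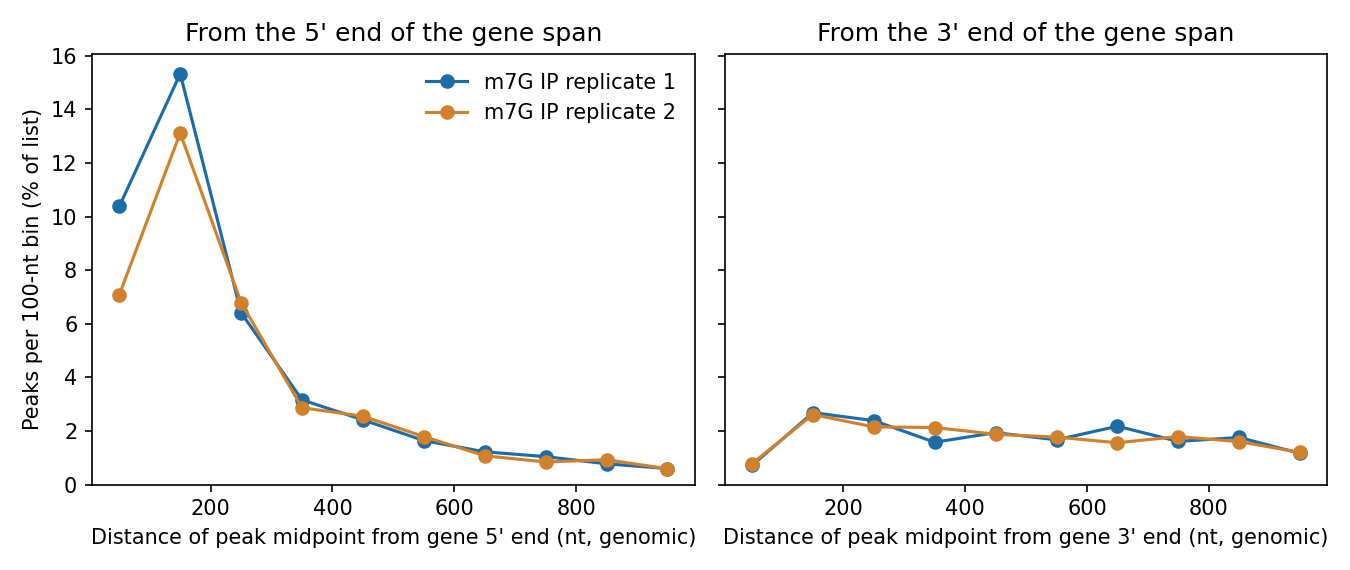
Share of each list's peaks (y axis, percent of the list) by distance of the peak midpoint from the 5' end (left) or 3' end (right) of the gene's span (x axis, nt in 100-nt bins from the end into the gene), for both IP replicates. The bin from 100 to 200 nt after the 5' end holds the most peaks in both lists (15.3% of replicate 1 and 13.1% of replicate 2), whereas no bin at the 3' end exceeds 2.68%.

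Called peaks at the 5' end also had higher folds. The median fold of 5'-end peaks was 4.95 in replicate 1, against 3.40 for all other peaks, a difference of 1.55. In replicate 2 it was 4.92 against 3.61, a difference of 1.31. Both differences passed a two-sided permutation test of medians (adjusted p = 2e-05 over 4 comparisons, from the smallest p that 100000 resamples can give). Examples were FOXA3, a hepatocyte transcription factor (folds 18.5 and 8.43), IDI1, an isomerase of sterol synthesis (14.8 and 6.33), and HRAS, a small GTPase (14.8 and 6.33); the last value of IDI1 and HRAS is the commonest fold of replicate 2. Peaks at the 3' end had lower median folds than all other peaks, 3.12 against 3.79 in replicate 1 (adjusted p = 0.015, permutation test) and 3.16 against 3.89 in replicate 2 (adjusted p = 0.0018). With 5'-end peaks left out, the difference at the 3' end was -0.375 (mean of the replicates) and no longer passed the test (p = 0.29, permutation test, the higher of the replicates). Peaks were the units in these tests, and peaks of 1 gene are not independent, so the p-values can be too small. Only called peaks enter the medians, and read depth is unknown. A difference in fold between positions can thus not be told apart from a difference in which folds could be called.

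The gene lists fixed beforehand were compared by the share of their genes with peaks in both lists. Splicing factors and endoplasmic reticulum (ER) chaperone genes stood out. Of the SR and hnRNP splicing factor genes with any peak, 17 of 18 (94.4%, 95% Wilson interval 74.2 to 99.0%) had peaks in both lists, compared with 51.5% of other genes (Fisher's exact test, two-sided, adjusted p = 0.0032 over 20 lists). They included HNRNPD (folds 11 and 14.2), SRSF9 (7.79 and 6.81), HNRNPL and PTBP1. The list's other 16 genes had no peak. Of the ER chaperone and unfolded protein response genes with any peak, 17 of 19 (89.5%, 68.6 to 97.1%) had peaks in both (adjusted p = 0.0079, Fisher's exact test). They included SDF2L1 (8.61 and 5.27), EDEM1, which acts in ER-associated degradation (37.1 and 3.87), XBP1 (2.76 and 3.24) and DNAJB11 (3.29 and 2.89), and 4 genes of the list had no peak. The folds of EDEM1 differ widely between the lists, and 37.1 equals, within rounding, the commonest fold of replicate 1 times a whole number. No list passed when the test was run on the 50% of each list of peaks with the smallest p, nor with 80% reciprocal overlap, nor within the genes of replicate 1 or of replicate 2 alone. Within replicate 1 genes, 17 of 17 of each list had peaks in both, against 77.4% of other genes (adjusted p = 0.188 for each, Fisher's exact test). Expression was not measured in these lists, so genes without m7G and genes without mRNA cannot be separated.

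The other 18 lists did not pass. Chromatin regulators had peaks in both lists for 16 of 21 genes (76.2%, adjusted p = 0.19, Fisher's exact test), among them the Polycomb subunit SUZ12 (folds 29.7 and 12.7), SMARCC2 of the SWI/SNF complex (16.3 and 12.7) and BPTF (9.44 and 15.2). Both folds of SUZ12 equal, within rounding, the commonest fold of their list times a whole number, as does the 12.7 of SMARCC2. Hepatocyte secreted proteins had 11 of 14 (78.6%, adjusted p = 0.29, Fisher's exact test), with low folds for APOE (2.15 and 2.24), the prothrombin gene F2 (1.33 and 1.43) and SERPINA1 (1.44 and 1.35). Genes of Hippo, Wnt and MAPK signalling had 15 of 22 (68.2%), including GSK3B (9.27 and 9.78) and DVL2 (6.92 and 5.93). RNA modification enzymes and readers had 8 of 11 (72.7%), including the RNA methyltransferase NSUN2 (5.77 and 8.19) and WTAP of the m6A writer complex (6.56 and 5.84). Stress granule and P-body genes had 7 of 15 (46.7%), including FXR2 (9.07 and 9.94) and ATXN2 (4.95 and 8.86). Cytosolic ribosomal protein genes had 10 of 19 (52.6%) and 44 of their 63 genes had no peak; RPLP1 had folds of 2.77 and 1.93 and RPL28 had 1.97 and 1.98. Translation factors had 12 of 20 (60.0%), including EIF4EBP2 (3.09 and 3.01) and the poly(A)-binding protein gene PABPC1 (2.49 and 2.09). In hepatocyte transcription factors the count was 6 of 9, in sterol and lipid synthesis 6 of 8, in aminoacyl-tRNA synthetases 3 of 8, in glycolysis 5 of 8, in oxidative phosphorylation 3 of 7, in cytosolic heat shock proteins 4 of 7, in the cytoskeleton 10 of 16, in DNA replication and mitosis 4 of 5, and in proteasome and ubiquitin genes 5 of 10. Of markers of other cell types, the immune list had peaks in CD68 and LYZ (2 of its 16 genes) and the endothelial and stellate list in ACTA2 (1 of its 16 genes), each in both lists.

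**Figure D3:**
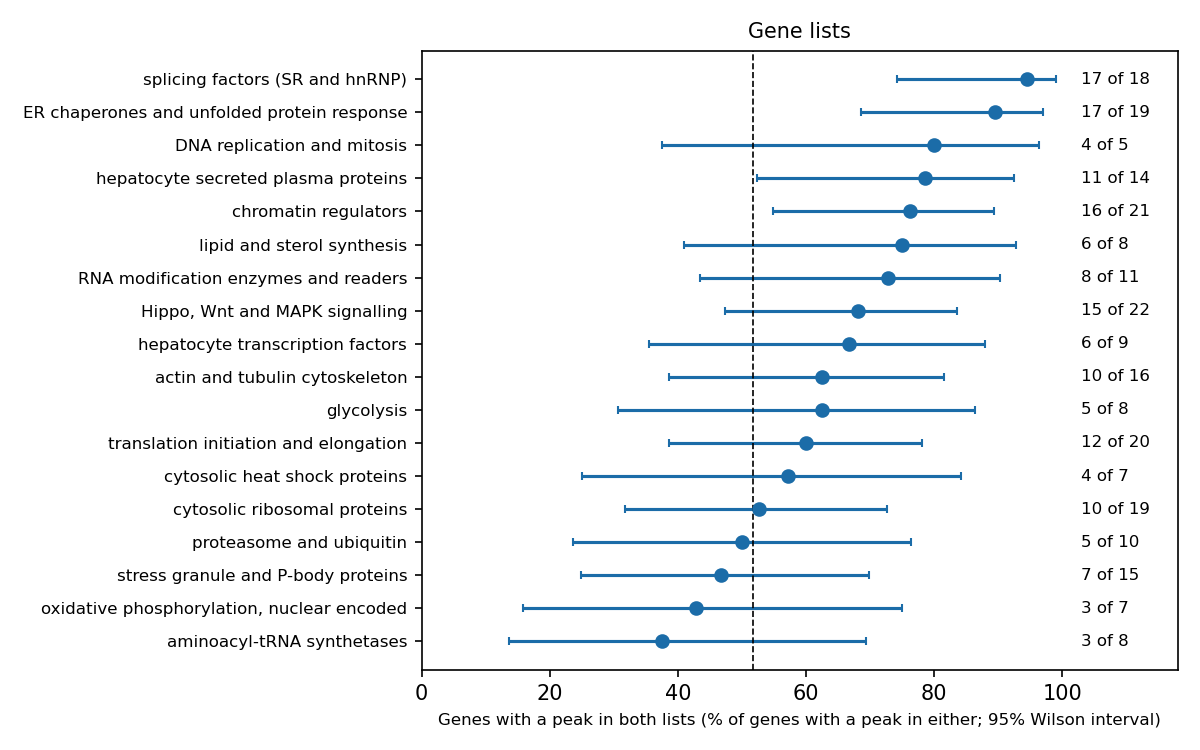
Share of each list's genes with a peak in both IP samples (x axis, percent of the list's genes with a peak in either sample, with 95% Wilson intervals), for lists with at least 5 such genes, with the counts at the right. The dashed line marks the 51.7% of all genes; splicing factors (17 of 18) and ER chaperones (17 of 19) lie farthest to its right.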

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

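The window of 500 nt, the restriction to gene spans over 10 kb, the restriction to single-block peaks and the exchange of distances as the test of overlap were chosen after seeing the data. Under every alternative that carried a test, the excess of peaks within 200 or 500 nt of the 5' end kept its direction and passed. So did the higher fold at the 5' end, the overlap of the lists above exchange and the agreement of folds. Without one replicate, the 5' share ranged from 21.6 to 27.4% and the fold difference from 1.31 to 1.55. Genes in both lists made up 51.7% of the union by name, and 45.3%, 46.5% and 19.3% when a peak had to be shared by 50% of the shorter peak, by 1 base or by 80% reciprocally; fewer genes pass by construction. With midpoints in the first 200 nt left out, the first 10% of the gene span held fewer peaks than the last 10%. The difference was -12.3 percentage points, against 15 with all peaks. The filter takes peaks from the 5' end only, so a drop is by construction, and a change of sign can be too. In replicate 1 it removed 27.4% of peaks, where the first 10% of the span held 43.9% and the last 10% 26.0%. In replicate 2 these shares were 21.6%, 38.7% and 26.6%. The sign thus does not tell which end the peaks beyond the first 200 nt lean to. Exons were not placed, no expected share was computed, and no filter was set at the 3' end. The fold difference at the 3' end was -0.375 without 5'-end peaks, against -0.70 with all peaks. It thus rested in part on the 5'-end peaks in the comparison group. With 5'-end peaks kept in that group, it was -1.56 (p = 0.0015, permutation test) for the 50% of each list with the smallest p. For shared peaks, with 5'-end peaks also kept, it was -1.0 (p = 0.0197, permutation test). The number of gene lists called was 2, and 3 with a shared base; it was 0 for the 50% of each list with the smallest p, 0 with 80% reciprocal overlap, 0 within replicate 1 genes and 0 within replicate 2 genes. At an unadjusted p under 0.05 these settings gave 1, 2, 3 and 3 lists in that order, against 3 by gene name (Fisher's exact test). For the smaller-p peaks, 80% reciprocal overlap and replicate 2 genes in turn, the odds ratio of the splicing list was 1.5, 4.23 and 11.1 (adjusted p 1, 0.064 and 0.051, Fisher's exact test) and that of the ER list 3.51, 2.46 and 5.53 (adjusted p 0.594, 0.489 and 0.088); within replicate 1 genes both lists had 17 of 17 genes in both, against 77.4% of others (adjusted p 0.188). Within the genes of 1 replicate the other genes start from a higher share, by construction; for the other settings the cause was not tested. The 5' share was 23.02% when every base was counted, a value without a test. Motifs and the choice of transcript were not run without sequence and transcript models, and a single replicate gives no value for genes in both lists. No paired analysis was possible because only the IP samples had values. Read depth is unknown and limits which peaks could be called.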

Other observations

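The tests of fold and 5' share by gene list, of the cap, of the ER genes, of recurring folds in the 25 genes named for high fold and of partners at equal length were chosen after the result was seen. Peaks in mRNAs of secreted plasma proteins, ribosomal proteins, translation factors, glycolysis and ER chaperones had low folds in both IP samples. The median fold was 1.25 in replicate 1 and 1.23 in replicate 2 for hepatocyte secreted proteins, 1.35 and 1.45 for cytosolic ribosomal proteins, 1.67 and 1.82 for translation factors, 1.38 and 1.5 for glycolysis and 1.66 and 1.94 for ER chaperones, against 3.71 to 3.8 in replicate 1 and 3.87 to 3.88 in replicate 2 for the peaks of all other genes. Each of these 5 lists passed a permutation test of the median log2 fold in both IP samples (highest adjusted p = 0.00067 over 20 lists). Peaks were the units, and some genes gave several. In replicate 1, 13 secreted protein genes gave 29 peaks and 17 ER genes gave 29. Peaks of 1 gene are not independent, so these p-values can be too small. In replicate 2 alone the cytoskeleton (2.09, adjusted p = 0.00067; replicate 1 2.57, 0.117) and cytosolic heat shock proteins (2.04, 0.0283; replicate 1 2.06, 0.149) also passed the permutation test, and the difference between replicates was not tested. The median folds of chromatin regulators (4.10 and 4.22) and of Hippo, Wnt and MAPK genes (4.45 and 4.32) did not pass. Only called peaks enter these medians, and expression and read depth are unknown. SERPINA1, a secreted protein gene, had folds of 1.44 and 1.35 at -log10 p of 245 and 152. FBXL19, by contrast, had folds of 37.1 and 31.6 at -log10 p of 4.4 and 4.34. Low folds of these gene lists can thus not be told apart from a difference in which folds could be called. Several mRNAs carried many peaks: SLC7A5, a neutral amino acid transporter, had 7 peaks in each list, the collagen gene COL27A1 had 6 and 7, and TNRC18 had 5 and 13. Ranked by the larger p of both lists, the smallest p-values were at FTH1, the ferritin heavy chain (-log10 p 916 and 738, folds 2.70 and 2.53), IGF2 (431 and 534) and A2M, alpha-2-macroglobulin (829 and 378); these genes were chosen after their values were seen. Of annotated protein-coding genes, those with peaks in both lists were most frequent on chromosome 16 (147 of 854, 17.2%, 95% Wilson interval 14.8 to 19.9%) and chromosome 19 (235 of 1451, 16.2%, 14.4 to 18.2%), and, of the 23 chromosomes with peaks, least frequent on chromosome X (35 of 848, 4.13%, 2.98 to 5.69%); expressed genes were not known.

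The excess of peaks at the 5' end was weighed against the length of gene spans. In genes with a span over 10 kb, 5'-end peaks outnumbered 3'-end peaks 11.5 to 1 in replicate 1 and 8.21 to 1 in replicate 2. The excess thus also held in long genes. Short spans place midpoints near both ends alike, so these ratios cannot test them as a cause of the excess. Fragments carrying the m7G cap, which the antibody could also bind, remain open. At least 59.0% of 5'-end peaks began within 50 nt of the gene's 5' end, but with a median length of 151 nt and a window of 200 nt the position of these peaks fixes much of that share. Internal m7G near the 5' end and sequence content there were not tested, and no biological explanation was tested.

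Peaks without a partner in the other list may be sites near the calling threshold. In the 25% of peaks with the smallest p, 94.4% of replicate 1 and 91.0% of replicate 2 peaks had a partner, and in the 25% with the largest p 34.7% and 15.3%. Longer peaks had a partner more often, 75.2% in replicate 1 and 56.0% in replicate 2 over 100 nt, and have smaller p (Spearman's rho of length with -log10 p 0.83 and 0.81). Among peaks of 100 nt or less the 50% with the smaller p had a partner more often, by 13.7 and 7.01 percentage points, and at equal length by 16.0 and 5.58 (permutation test within lengths, p = 0.0001, the smallest 10000 resamples can give, and 0.0085; 15.1 and 19.0 over every length with at least 20 peaks, p = 0.0001 for both), which argues against length as the whole cause but not as a part of it. No biological explanation was tested, since the labels put both lists in 1 group.

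Fold values recurred within each list: 107 replicate 1 peaks had a fold of exactly 7.42 and 196 replicate 2 peaks a fold of 6.33. A hypothesis is that folds are ratios of small whole numbers times 1 constant per list, as few reads behind a peak could give. Folds equal to the commonest fold times a ratio of whole numbers up to 10 made up 28.8% of replicate 1 and 32.4% of replicate 2, against medians of 6.29% and 7.05% for 1000 other constants (percentile 99.8 in replicate 1 and 99.9 in replicate 2). The highest share of another constant was 29.2% and 32.5%, at constants of 7.425 and 6.327, which lie next to the commonest folds. Of the 25 genes named for high fold, 16 in replicate 1, 13 in replicate 2 and 11 in both had such a fold, among them PKP4, FBXL19, HDGFL2, ROGDI, CLK2 and PI4K2B; 1000 pairs of other constants gave a median of 0 and at most 7 genes in both.

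A further hypothesis is that peaks of ER chaperone and unfolded protein response genes lie at the 5' end more often than other peaks. It was drawn from the counts it was tested on, 14 of 29 peaks in replicate 1 and 11 of 27 in replicate 2. These were 48.3% and 40.7%, against 27.2% and 21.5% of other peaks. The counts leave the hypothesis open. In Fisher's exact test p was 0.0192 and 0.0307 before and 0.222 and 0.614 after adjustment over 20 lists. Peaks were the units, and peaks of 1 gene are not independent, so these p-values can be too small.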
